A study of Laodelphax striatellus with 6 samples.

How the data were processed

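Poly(A) RNA from whole Laodelphax striatellus was made into strand-marked libraries by second-strand uracil labelling, per the labels' protocols. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2, without saying which step each served. The genome build and the tool that gave the deposited values are not given in the sources used here. The gene identifiers have the form that the Trinity assembler gives to genes assembled from reads, and protein descriptions with a best-hit species stand beside 25802 of the 59004 rows. No coordinates, GO terms or KEGG terms were used here.

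The deposited TPM values were made by the authors for each library, to 2 decimals. The table is named for FPKM, but all 6 libraries sum to the same total within rounding, which TPM does and FPKM does not, so the values were read as TPM. The test planned for log2(FPKM + 1) was applied unchanged to log2(TPM + 1). TPM is relative to each library's total, so a large change in a few abundant transcripts shifts all others. It keeps no depth, so the number of reads behind a value is unknown, and an exact 0 can be an estimate that failed. The authors' mean of each group, deposited beside the libraries, were not used. A single gene can be split over several assembled rows, and rows of near-identical families (P450, ribosomal and cuticle proteins) can share reads, so their separate values are uncertain.

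Samples were grouped by their titles into 3 control and 3 asarone libraries. Pairs of libraries had identical values in 1.43% to 2.69% of rows, and no pair was treated as 1 library. Rows with a mean of at least 1 TPM over the 6 libraries were tested (24816 rows). Of these, 42.1% had no description. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust) on log2(TPM + 1), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on this log2(TPM + 1) scale, which understates the change of low genes. Values of single genes are means with SD over 3 libraries. Confidence intervals are limma's at 95%.

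The 17 gene lists, fixed before the data were examined as text patterns on the protein description, were tested with limma's camera (preset correlation 0.01, and an estimated correlation) and with fry, adjusted over the 17 lists. The 5 detoxification lists are cytochrome P450, glutathione S-transferase, carboxylesterase, UDP-glycosyltransferase and ABC transporter. The others are antioxidant enzymes, heat shock proteins, cuticle and chitin, cytosolic ribosomal proteins, oxidative phosphorylation, digestive proteases and lipases, yolk and eggshell, sperm and cilium, muscle, immunity, neural targets and hormones. The summed TPM of a list was compared by limma on the log2 scale and by an exact permutation test.

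The genes named were chosen by a rule written before the data were examined. It took the 5 higher and 5 lower genes with a mean of at least 5 TPM, groups that did not overlap and an informative description, ranked by unadjusted p because fewer than 20 genes passed. It also took, from each list with no member past the threshold, the member with the smallest p. TRINITY_DN13091_c0_g1, the abundant P450 and ABC transporter transcripts, glutathione S-transferase D2, heat shock protein 90-2 and the other heat shock members named were chosen after their values were seen. So was the definition of genes found in 1 library only.

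The procedure was tested on data simulated from the real means and spread, with 200 genes changed in each of 20 simulations; 0.0276% of unchanged genes were called. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, trimmed-mean scaling, quantile normalization, a replicate block, limma without trend or robust, leaving out each library and an estimated correlation. After the data were seen, 4 were added: summing rows with the same description, keeping planthopper best hits only, leaving out rows found in 1 library only, and an estimated correlation under each alternative. Figures were drawn with matplotlib.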

Results

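The small brown planthopper, Laodelphax striatellus, is a sap-feeding insect pest of rice. Whole bodies were profiled by poly(A) RNA sequencing with strand-marked libraries, in 3 untreated control libraries and 3 libraries from insects treated with β-asarone, a plant phenylpropanoid. The study concerned the detoxification response to this compound. The labels give neither its dose nor the time of exposure, nor the sex, stage or number of insects in a library. They also do not say whether the 3 libraries of a group came from separate groups of insects, so the p-values measure the spread between these libraries, which may be technical. The table lists 59004 assembled genes in TPM, each transcript's length-corrected share of its library, of which 25802 carry a protein description and its best-hit species. Between 47664 and 49577 assembled genes had a value above 0 in a library. The sequencing depth behind the values is unknown, because TPM keeps no depth, so no counting interval is given.

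The libraries did not separate by treatment. Spearman correlations of log2(TPM + 1) averaged 0.809 over the 6 pairs of the same group (0.785 to 0.838) and 0.812 over the 9 pairs of different groups (0.782 to 0.844). The first principal component held 30.1% of the variance. Control replicates 1, 2 and 3 stood on it at -51.4, 56.7 and 12.1. Asarone replicates 1, 2 and 3 stood in the same order, at -54.0, 33.5 and 3.08. The second component held 23.6% and set asarone replicate 2 apart, at -74.9. Control replicate 2 also stood apart, at 56.7 on the first component and 43.5 on the second. Its tested genes had a median of 2.23 TPM, against 2.85 to 3.37 TPM in the other libraries, and its median-of-ratios size factor was 0.783, against 1.00 to 1.13. Asarone replicate 2 also held 560 assembled genes found in it only, defined as at least 2 TPM there and at most 5% of that value in each other library. The other 5 libraries held 100 to 228 such genes each. Of the 560 genes, 268 had a best hit outside planthoppers and 46 were described as cytosolic ribosomal proteins, against at most 15 and 2 in any other library. Together they made up 0.427% of that library's TPM.

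**Figure D1:**
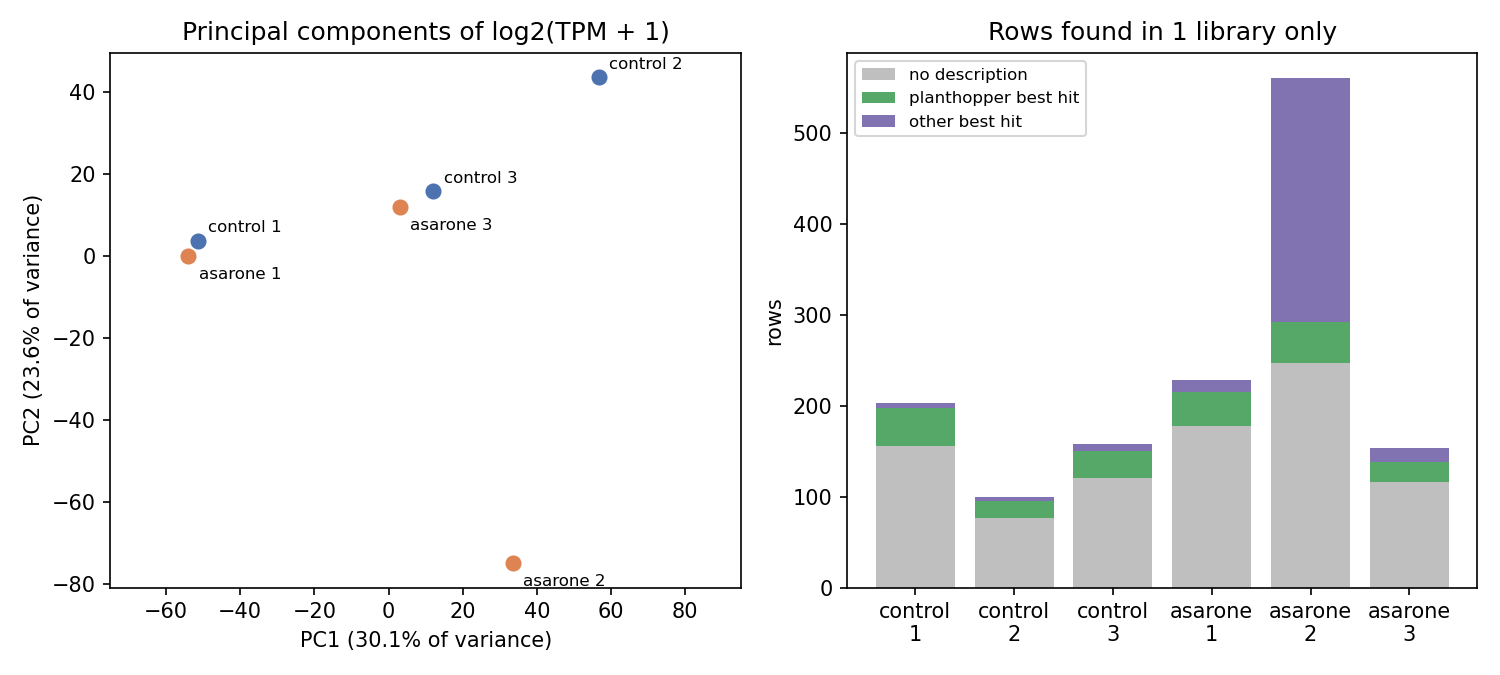
Left, the 6 libraries on the first 2 principal components of log2(TPM + 1) over the tested genes, coloured by group (control blue, asarone orange). Right, the number of assembled genes found in 1 library only, stacked by the kind of best hit; asarone replicate 2 holds 560, the other libraries 100 to 228.

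The comparison of treated with control insects asked which genes, and above all which detoxification genes, respond to β-asarone. Whole-body expression of the detoxification families differed by less than the spread between libraries, and 1 of 24816 tested genes passed the threshold. That gene, TRINITY_DN13091_c0_g1, has no protein description. It was listed at 0 in all 3 control libraries and at 6.85, 10.44 and 8.34 TPM in asarone replicates 1, 2 and 3 (limma, adjusted p = 0.0374). The next smallest adjusted p was 0.32. Across all tested genes 860 had an unadjusted limma p under 0.05, where 1240.8 would be expected by chance, and 494 of them were higher and 366 lower in treated insects. Groups that did not overlap were seen for 8.66% of the tested genes, against 10% by chance. The adjusted p of TRINITY_DN13091_c0_g1 was 0.197 to 0.532 on leaving out any 1 of the 6 libraries, 0.286 with a pseudocount of 0.1, 0.0977 with no filter and 0.0758 to 0.0811 with 3 other scalings. Leaving out a library or adding another pseudocount does not alter the values listed for this gene. Its tested log2 change does depend on the pseudocount, because all 3 control values are 0. Simulated data of this design had 200 genes changed at once and noise drawn independently for each gene. Log2 changes of 1, 2 and 3 were called for 19.3%, 81.9% and 93.5% of genes with a mean of at least 5 TPM. With fewer genes changed the adjusted threshold is harder to reach, so these shares are too high for a lone gene. A 2-fold change of a single gene would mostly have been missed.

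The 5 detoxification lists held 68 tested genes, and 0 passed the threshold over all genes tested or adjusted over the list alone. Cytochromes P450, the oxidases of the first phase of xenobiotic metabolism, summed to 1872 ± 232 TPM (SD, n = 3) in control and 1918 ± 216 TPM (SD, n = 3) in treated insects, a ratio of 1.03 with a 95% limma interval of 0.812 to 1.3. Glutathione S-transferases, which conjugate electrophiles to glutathione, gave a ratio of summed TPM of 0.973 (0.825 to 1.15). Most of this sum, 550 TPM in control and 536 TPM in treated insects, was glutathione S-transferase D2 (TRINITY_DN37200_c1_g1) at 401 and 368 TPM. Of the 7 members 6 were higher and 1 lower in treated insects. The ratio was 1.05 (0.867 to 1.27) for carboxylesterases, which hydrolyse ester insecticides. It was 1.17 (0.84 to 1.63) for UDP-glycosyltransferases and 1.02 (0.822 to 1.27) for ABC transporters, some of which export conjugates. The ABC list summed to 185 TPM in control and 188 TPM in treated insects. Its most abundant members were of sub-family F (TRINITY_DN98_c0_g1, 57.1 and 61.5 TPM) and sub-family D (TRINITY_DN16548_c0_g2, 33.6 and 31.5 TPM). This sum therefore does not measure conjugate exporters alone. Exact two-sided permutation tests of the 5 sums gave p-values of 0.4 to 1, where the smallest p this design allows is 0.1. Of the 68 genes, 38 were higher and 30 lower in treated insects, and the split was 28 and 40 after median-of-ratios scaling, 31 and 37 after trimmed-mean scaling and 33 and 35 after quantile normalization.

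**Figure D2:**
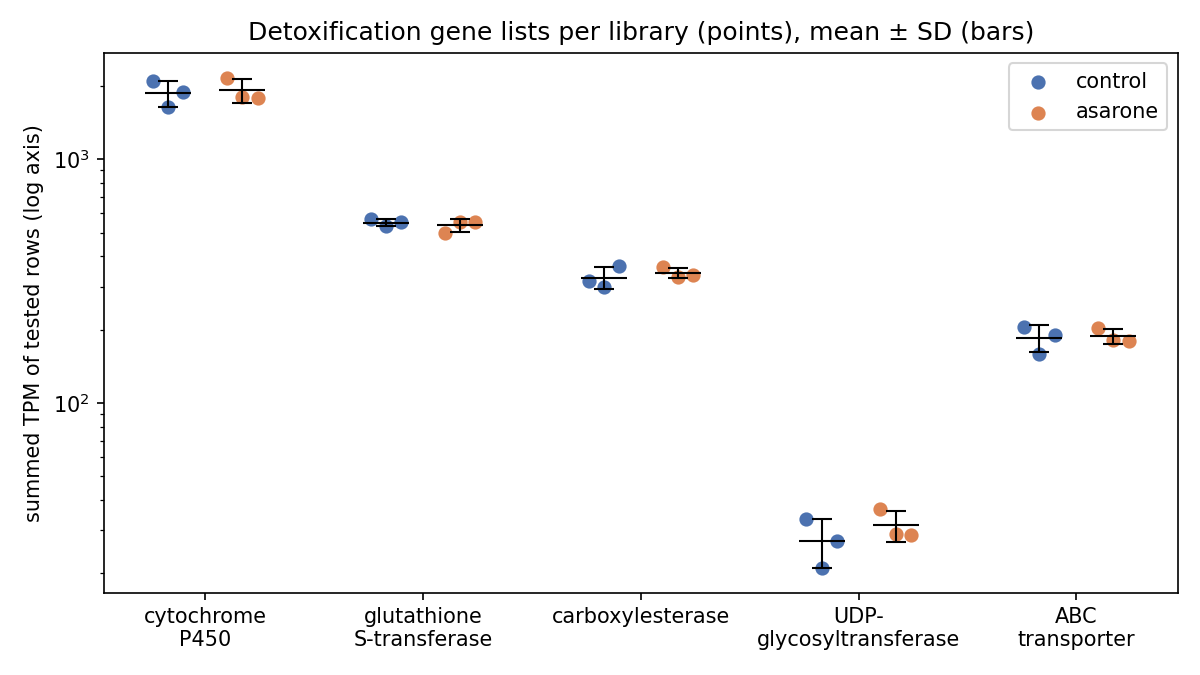
Summed TPM (log axis) of the tested genes of each detoxification list in each library (points, control blue and asarone orange), with the mean and SD of 3 libraries as bars. Both groups overlap in all 5 lists, for example 1872 ± 232 against 1918 ± 216 TPM for the cytochromes P450.

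The most abundant P450 transcripts, both with CYP6ER2 of this species as best hit, stood at 557 ± 68.2 and 563 ± 74.7 TPM (TRINITY_DN3081_c0_g1) and at 476 ± 47.7 and 540 ± 71.1 TPM (TRINITY_DN8594_c0_g1) in control and treated insects (SD, n = 3). Glutathione S-transferase S3 (TRINITY_DN919_c0_g1) was at 96.0 ± 0.713 and 110 ± 12.4 TPM, esterase E4 (TRINITY_DN4892_c0_g1) at 15.5 ± 3.18 and 20.9 ± 3.77 TPM, and UGT5 (TRINITY_DN13659_c0_g2) at 15.0 ± 4.85 and 18.3 ± 3.46 TPM. CYP6FL2 (TRINITY_DN23899_c0_g1) was at 2.58 ± 2.36 and 0.567 ± 0.503 TPM. Among the 68 genes, 1 had an unadjusted limma p under 0.05: a homologue of multidrug resistance protein 49 (TRINITY_DN19304_c0_g1), an ABC transporter, at 2.02 ± 0.592 TPM in control and 0.367 ± 0.0416 TPM in treated insects (log2 change -1.13, SE 0.25, limma adjusted p = 0.858). Limma's camera test compares the genes of a list with the other tested genes, so a list called lower is lower relative to these. The median log2 change of all tested genes was 0.0835. As sets, none of the 5 lists passed this camera test with a preset correlation of 0.01, with adjusted p-values of 0.108 to 0.563. The ABC transporters passed it as lower after median-of-ratios scaling (adjusted p = 0.0414), after trimmed-mean scaling (0.043) and without control replicate 2 (0.0422). With an estimated correlation these became adjusted p = 0.755, adjusted p = 0.73 and adjusted p = 0.883. The cytochromes P450 passed it as lower when genes with the same description were summed (0.0338), an alternative chosen after seeing the data, and not with an estimated correlation (adjusted p = 0.436).

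Heat shock proteins, the chaperones that refold damaged proteins, gave the smallest camera p among the 17 lists. Of 31 tested members 22 were lower and 9 higher in treated insects, with a median log2 change of -0.14 (camera with the preset correlation, adjusted p = 1.85e-05). The list did not pass with an estimated correlation (adjusted p = 0.731) or in fry (adjusted p = 0.259). No member passed over all genes tested, while 6 passed adjusted over the list alone, all lower. They were heat shock protein cognate 70-1, HSP28.7, heat shock protein 90-2, the 105 kDa heat shock protein (best hit in the sea slug Elysia marginata), heat shock protein 70-8 and the mitochondrial heat shock protein 78. Heat shock protein cognate 70-1 (TRINITY_DN112_c0_g2) was at 71.7 ± 6.86 TPM in control and 45.3 ± 3.83 TPM in treated insects (log2 change -0.65, SE 0.14). The small chaperone HSP28.7 (TRINITY_DN12843_c3_g1) was at 297 ± 30.1 and 186 ± 19.3 TPM (log2 change -0.67, SE 0.15), and heat shock protein 90-2 (TRINITY_DN5693_c0_g1) at 103 ± 10.03 and 67.0 ± 4.96 TPM (log2 change -0.61, SE 0.14). The summed TPM of the whole list was 4733 ± 502 in control and 4171 ± 462 in treated insects (SD, n = 3; exact two-sided permutation p = 0.3). A gene of the list was among those found in asarone replicate 2 only. The median of the list minus that of all tested genes was -0.222 on the log2 scale, and it became -0.128 after quantile normalization, -0.108 without control replicate 2, -0.119 without asarone replicate 1 and -0.379 without control replicate 1. With no filter on low values it was -0.0334 and the call was lost (adjusted p = 0.272).

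**Figure D3:**
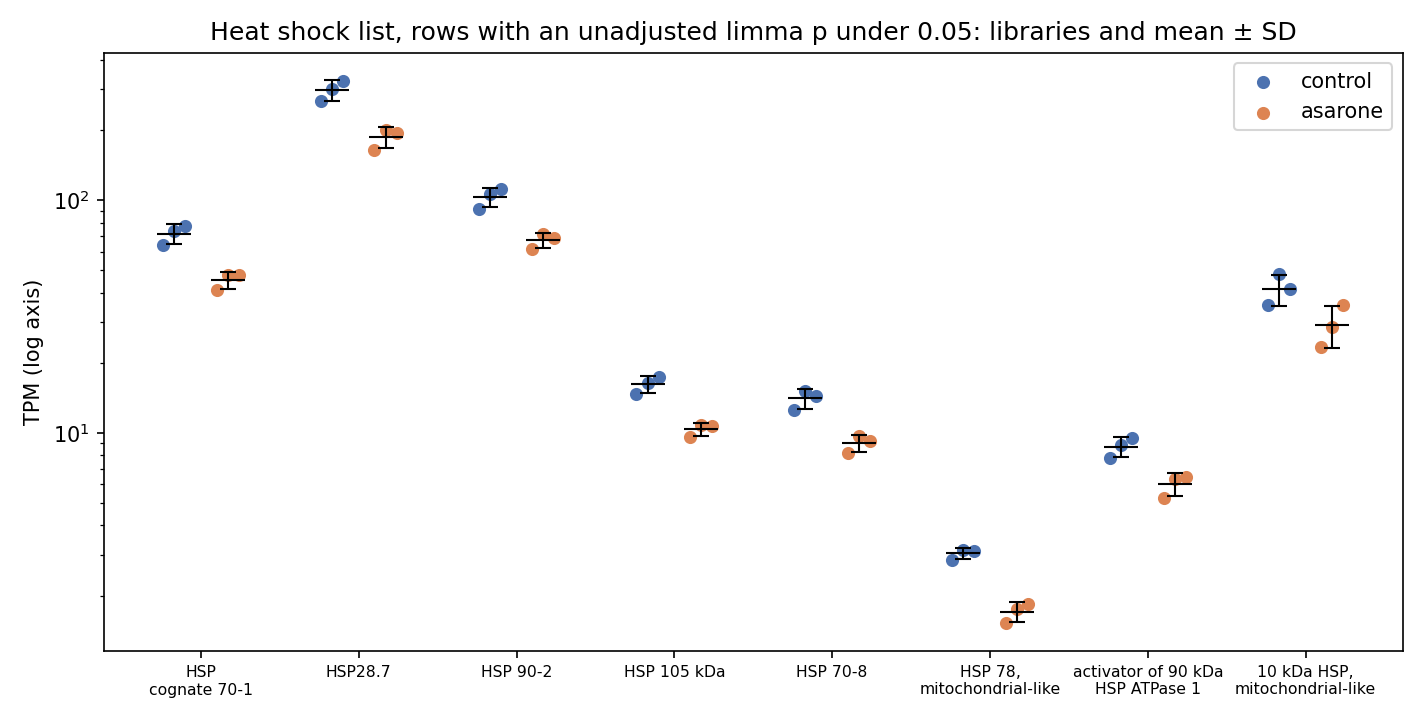
TPM (log axis) of the 8 heat shock list members with an unadjusted limma p under 0.05 in each library (points, control blue and asarone orange), with the mean and SD of 3 libraries as bars. All 8 are lower in treated insects, with log2 changes of -0.675 to -0.469; they were chosen by their p.

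Cuticle and chitin genes, which build the exoskeleton, were lower in 42 of 55 cases, with a median log2 change of -0.21 and 0 members past the threshold. The list passed camera with the preset correlation (adjusted p = 0.000235) but not with an estimated correlation (adjusted p = 0.731), nor without asarone replicate 2 (adjusted p = 0.242). A cuticular protein (TRINITY_DN41902_c0_g1) was at 291 ± 44.4 TPM in control and 193 ± 28.7 TPM in treated insects. Cytosolic ribosomal proteins also passed with the preset correlation (adjusted p = 0.000609) and not with an estimated one (adjusted p = 0.778). Their median log2 change was -0.11 and their mean 0.13, which differ in sign. Of the 187 tested members, 28 were found in asarone replicate 2 only, and over the 158 members not found in 1 library only the mean was -0.04. The list's direction turned without control replicate 2 (adjusted p = 0.579) and without asarone replicate 1 (0.659), and the call was lost with no filter (0.544) and after quantile normalization (0.325). A fragment of ribosomal protein P0 (TRINITY_DN13429_c0_g1) was at 225 ± 37.6 TPM in control and 409 ± 38.5 TPM in treated insects (log2 change 0.87, SE 0.17, limma adjusted p = 0.809).

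Oxidative phosphorylation genes, of the mitochondrial respiratory chain, summed to 55500 ± 5220 TPM in control and 57480 ± 4690 TPM in treated insects, a ratio of 1.04 with a 95% limma interval of 0.848 to 1.27. They were lower in 50 of 77 cases with a median log2 change of -0.07 and a mean of -0.01, opposite in sign to the sum (adjusted p = 0.00243 with the preset correlation, adjusted p = 0.731 with an estimated correlation), and 4 of them were found in asarone replicate 2 only. The call was lost without control replicate 2 (0.579), without asarone replicate 1 (0.33), with no filter (0.272) and after quantile normalization (0.119). Antioxidant enzymes, which remove peroxides and superoxide, were lower in 14 of 20 cases (camera adjusted p = 0.0414 with the preset correlation, adjusted p = 0.731 with an estimated correlation). Their median log2 change was -0.08, their mean 0.02 and the ratio of their summed TPM 1.02 (95% limma interval 0.854 to 1.21). Their call was lost without control replicate 2 (0.793), without asarone replicate 1 (0.558), with no filter (0.32), with a mean of at least 5 TPM (0.273), after quantile normalization (0.193) and with planthopper best hits only (0.702), and 1 member was found in asarone replicate 2 only. A homologue of glutaredoxin-C4 (TRINITY_DN50543_c0_g1), with an ant as best hit, was at 11.2 ± 1.83 TPM in control and 8.49 ± 0.893 TPM in treated insects. NADH dehydrogenase 1 alpha subcomplex subunit 2 (TRINITY_DN10987_c0_g1), of respiratory complex I and with a wasp as best hit, was at 5.20 ± 1.00 and 3.20 ± 0.370 TPM.

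The other 7 lists did not pass. Their adjusted camera p with the preset correlation was 0.911 for digestive proteases and lipases, 0.52 for yolk and eggshell, 0.146 for sperm and cilium, 0.146 for muscle, 0.536 for immunity, 0.563 for neural targets and 0.52 for hormones. All 12 sperm and cilium genes were higher in treated insects, with a median log2 change of 0.23, and 11 of the 12 were higher under each of the 3 other scalings. Their estimated correlation was 0.594, so they are not 12 independent observations. Their summed TPM was 39.9 ± 17 in control and 45.5 ± 9.61 in treated insects, a ratio of 1.19 (limma interval 0.71 to 1.99). The exact two-sided permutation test of this sum gave p = 0.6. The highest sum, 59.4 TPM, was in control replicate 1. The sex and stage of the insects, which set the level of such genes, are not known here. This list passed as higher without control replicate 1 (adjusted p = 0.00457) and without asarone replicate 2 (0.0341), but not with an estimated correlation (adjusted p = 0.802 and adjusted p = 0.825). Its direction turned without control replicate 3 (0.777). Axonemal dynein intermediate chain 4 (TRINITY_DN23935_c0_g1) was at 1.99 ± 0.429 TPM in control and 3.03 ± 0.789 TPM in treated insects. Muscle myosin heavy chain (TRINITY_DN1_c1_g1) was at 370 ± 29.0 and 291 ± 36.7 TPM, and the muscle list passed as lower after median-of-ratios scaling (0.0374), after trimmed-mean scaling (0.043), without control replicate 2 (0.0112) and without asarone replicate 1 (0.00532). With an estimated correlation the muscle list passed in none of these (adjusted p = 0.755, 0.73, 0.883 and 0.901). The antimicrobial peptide defensin B (TRINITY_DN5531_c0_g1) was at 8.39 ± 2.72 and 16.4 ± 3.72 TPM (log2 change 0.91, SE 0.26, limma adjusted p = 0.98). The ryanodine receptor (TRINITY_DN3356_c0_g1), a calcium channel, was at 4.65 ± 0.995 and 3.95 ± 0.490 TPM, and the vitellogenin receptor (TRINITY_DN15698_c0_g4) at 1.38 ± 0.417 and 1.83 ± 0.0945 TPM. The ecdysone-inducible receptor E75 (TRINITY_DN374_c1_g1) was at 1.19 ± 0.438 and 2.13 ± 1.07 TPM, and a serine carboxypeptidase-like gene with a best hit in the sponge Amphimedon queenslandica (TRINITY_DN33909_c0_g1) at 1.85 ± 0.315 and 1.27 ± 0.0802 TPM.

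**Figure D4:**
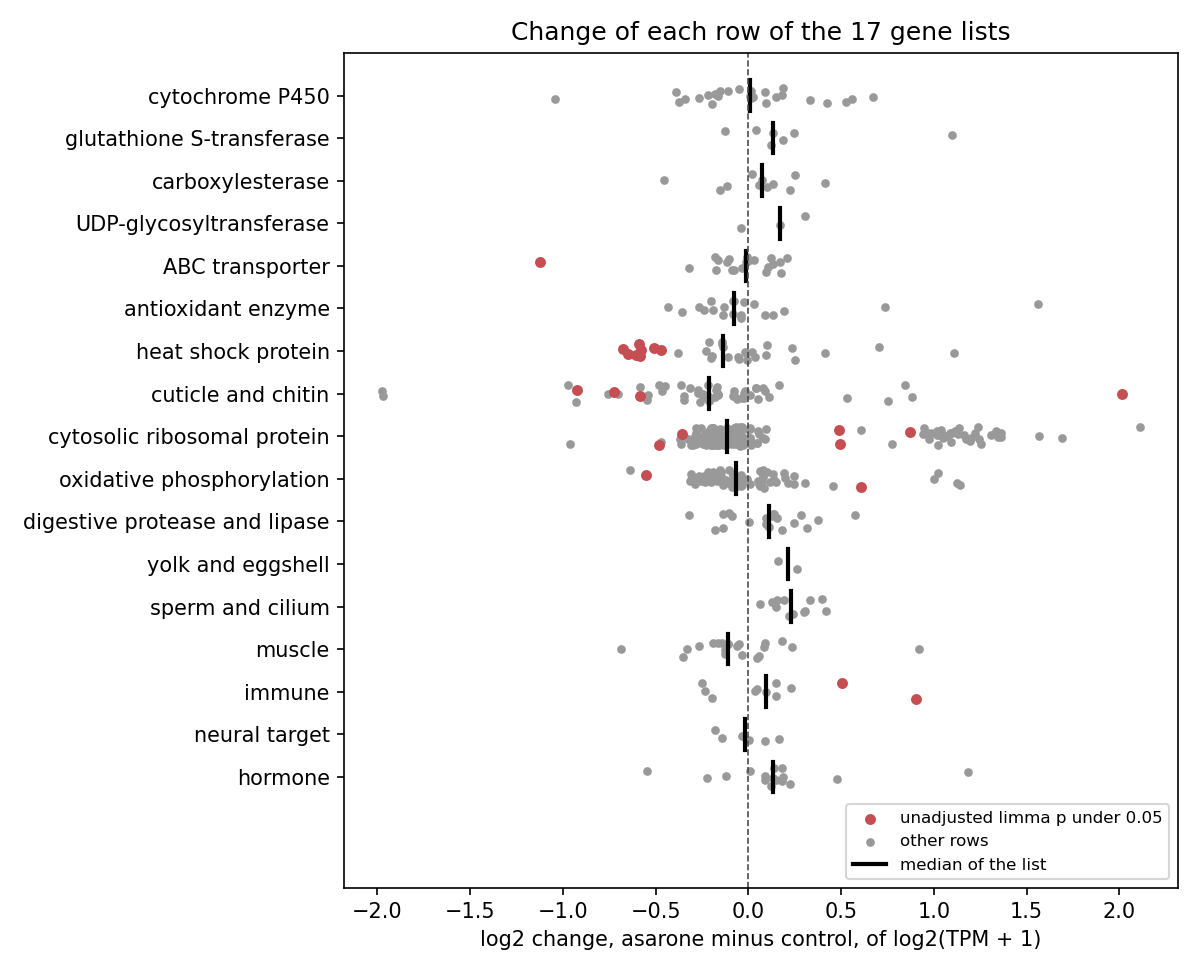
Change in log2(TPM + 1), asarone minus control, of each tested gene (points) in the 17 lists, with list medians as black bars and genes with an unadjusted limma p under 0.05 in red. The heat shock list has 8 red points, all below 0, and the 5 detoxification lists have 1.

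Of the genes with informative descriptions, a mean of at least 5 TPM and groups that did not overlap, 62 were higher and 77 lower in treated insects, and none passed the threshold. The smallest unadjusted p on the lower side belonged to TRINITY_DN8982_c0_g1, whose best hit is the Pol polyprotein of the Drosophila melanogaster retroelement opus. This gene was at 25.4 ± 1.93 TPM in control and 11.7 ± 1.39 TPM in treated insects (log2 change -1.06, SE 0.15, limma adjusted p = 0.542). It was followed by zinc finger protein 771 (TRINITY_DN4090_c1_g1) at 8.67 ± 1.85 and 2.39 ± 0.754 TPM (log2 change -1.52, SE 0.23, limma adjusted p = 0.695). Peptidyl-prolyl cis-trans isomerase D (TRINITY_DN45_c0_g1), a co-chaperone whose best hit is the lancelet Branchiostoma floridae, was at 18.2 ± 2.33 and 10.2 ± 1.49 TPM. The 720 tested genes with a best hit in 1 of 45 genera outside the arthropods, a set chosen after seeing the data, had a median log2 change of -0.16. On the higher side stood a fragment of mitochondrial cytochrome oxidase subunit I (TRINITY_DN38278_c0_g1) at 5.84 ± 2.72 and 15.8 ± 3.64 TPM (log2 change 1.35, SE 0.33, limma adjusted p = 0.972). Vesicle-fusing ATPase 1 (TRINITY_DN14632_c0_g1), of membrane traffic, was at 7.72 ± 1.49 and 12.8 ± 0.990 TPM, and the glycolytic enzyme hexokinase (TRINITY_DN33364_c0_g1) at 4.14 ± 0.654 and 6.85 ± 0.313 TPM.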

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

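The alternatives that sum rows of one description, keep planthopper best hits only or leave out rows found in 1 library only were chosen after seeing the data. The number of genes past the threshold was 1 and became 0 with a pseudocount of 0.1, with no filter, with a mean of at least 5 TPM (the called gene has a mean of 4.27 TPM, so it was not tested there), under median-of-ratios, trimmed-mean and quantile scaling, with planthopper best hits only (the called gene has no best hit, so it was not tested there) and without each single library (0 to 0). It stayed at 1 with a pseudocount of 0.5, without trend or robust, with descriptions summed and without rows found in 1 library only. The number with an unadjusted p under 0.05 was 860, and it was 1888 with no filter (58378 rows tested), 202 with a mean of at least 5 TPM (8270 rows), 284 with planthopper best hits only (12248 rows) and 769 to 1477 on leaving out 1 library, the highest without control replicate 1. With a replicate block 0 genes passed, 1039 had an unadjusted p under 0.05 and the antioxidant list lost its call (adjusted p = 0.0525). Same-numbered libraries had deviations correlated at 0.157, 0.0814 and -0.035, and replicates 1 and 2, but not 3, correlated best with their own number. The replicates of both groups also stood in the same order on the first principal component, so a pairing by number is possible. The main test leaves out any such pairing, which would add to the spread it tests against. Adjusted camera p-values that crossed the threshold were as follows. With no filter the antioxidant list gave 0.32, heat shock 0.272, ribosomal 0.544 and oxidative phosphorylation 0.272. With a mean of at least 5 TPM the antioxidant list gave 0.273. Median-of-ratios scaling brought ABC transporters to 0.0414 and muscle to 0.0374, and trimmed-mean scaling brought both to 0.043. Quantile normalization gave 0.193 for antioxidant, 0.325 for ribosomal and 0.119 for oxidative phosphorylation. An estimated correlation ended all 5 calls, at 0.731 for antioxidant, heat shock, cuticle and oxidative phosphorylation and 0.778 for ribosomal. With an estimated correlation under each alternative as well, also chosen after seeing the data, 0 lists passed in any setting (smallest adjusted p = 0.142). Summed descriptions brought cytochrome P450 to 0.0338, and planthopper best hits only took antioxidant to 0.702. Leaving out 1 library gave ranges of 0.00457 to 0.777 for sperm and cilium, 0.0422 to 0.342 for ABC transporters, 0.00628 to 0.793 for antioxidant, 1.22e-13 to 0.659 for ribosomal, 6.05e-06 to 0.579 for oxidative phosphorylation, 0.00532 to 0.832 for muscle, and 1.29e-06 to 0.242 for cuticle, whose call was lost without asarone replicate 2. For heat shock the range was 3.29e-06 to 0.0112, with the call held each time. Of lists that were never called, the direction turned for digestive proteases and lipases with a pseudocount of 0.1 (0.904) and with no filter (0.746), and for neural targets with a mean of at least 5 TPM (0.973). On leaving out 1 library it turned for digestive proteases and lipases (range 0.529 to 0.894), neural targets (0.228 to 0.962), hormones (0.371 to 0.825) and carboxylesterases (0.447 to 0.822). The causes of these lost, gained or turned list calls were not tested. The 408 log2 changes compared under alternatives were those of 25 genes, picked by smallest p under the rule or past the threshold. Other genes named after their values were seen were not included. None of the 408 turned in direction and none newly passed. Where the groups of a gene do not overlap, leaving out 1 library cannot turn its direction. Enrichment of annotated terms was not run because no terms were used, and count-based tests were not run because the values are TPM. Depth is unknown, so low genes have an error that cannot be separated from biology.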

Other observations

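The tests of explanations and of other splits in this part were chosen after the results were seen, as were the comparison over planthopper best hits and the estimated correlation under alternatives, while quantile normalization was planned before the data were examined. Among the immune genes the transcription factor dorsal (TRINITY_DN14113_c0_g1), which relays Toll signals, was at 1.08 ± 0.0985 TPM in control and 1.96 ± 0.317 TPM in treated insects, beside defensin B (TRINITY_DN5531_c0_g1) at 8.39 ± 2.72 and 16.4 ± 3.72 TPM. Both had an unadjusted limma p under 0.05, 0 immune genes passed adjusted over the list alone, and dorsal was named after its values were seen. Assembled copies of ribosomal protein L19 with a planthopper best hit (TRINITY_DN34299_c0_g1 and TRINITY_DN42300_c0_g1) were higher in treated insects, at 11.8 ± 1.93 and 17.1 ± 3.06 TPM and at 61.7 ± 7.22 and 86.8 ± 7.64 TPM, while a copy with a beetle best hit (TRINITY_DN11993_c0_g1) was lower, at 5.59 ± 0.883 and 3.70 ± 0.417 TPM. These copies were also named after their values were seen, and none passed the threshold.

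The genes found in asarone replicate 2 only are a first pattern to follow up. They include 46 ribosomal protein rows, against at most 2 in any other library, and of the 43 ribosomal proteins named, 35 have another row of at least 1 TPM in all 6 libraries. Absence by chance of rare transcripts is argued against by their median level, 1.63 times the highest of the other libraries. It is not excluded, because the cut-off for this ratio was set after the data were seen and depth is unknown. RNA of another organism in that library is a candidate explanation that stays open, since these counts prompted it. The ribosomal rows, which would be among the most abundant of an organism, had a median of 6.42 TPM. The other rows found there only had a median of 4.93 TPM, a ratio of 1.3. This ratio cannot decide the question, because only rows of at least 2 TPM were taken, which leaves out the low rows of such an organism. No biological explanation was tested. Rows with a planthopper best hit were little more frequent, 45 of them there against 18 to 42 in each other library. Rows with another best hit numbered 268 there against 5 to 15. Some planthopper rows were high there, such as TRINITY_DN431_c0_g1 at 234 TPM in asarone replicate 2 and at most 0.52 TPM elsewhere.

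The lower heat shock list is a second pattern, and no explanation tested for it was excluded. Scaling of the libraries stays open: the list's median relative to all tested genes was -0.222, and it was -0.252 and -0.248 (adjusted p = 0.000333 and 3e-04 at the preset correlation) under median-of-ratios and trimmed-mean scaling, which move all genes of a library nearly alike, but -0.128 after quantile normalization (adjusted p = 0.00346 at the preset correlation and 0.699 with an estimated one). For a lower share of another organism, the 720 rows with a distant best hit had a median log2 change of -0.158 (camera p = 1.36e-20 at the preset correlation and 0.165 with an estimated one). Their summed TPM, 6385 ± 248 in control and 6253 ± 557 in treated insects, differed by less than the spread. Without rows found in 1 library only, 654 rows summed to 6385 ± 248 in control and 6016 ± 154 in treated insects. That difference exceeded either SD and was not tested. Among planthopper best hits the list was lower at an adjusted camera p of 1.39e-07 with the preset correlation and 0.142 with an estimated one (0.00837 unadjusted). These 23 members had a median log2 change of -0.055, and it was -0.157 relative to all planthopper rows. Of them 16 were lower and 7 higher, and 5 had an unadjusted limma p under 0.05. The other 8 members had a median of -0.169, and 3 had such a p. The lowering was thus not confined to other best hits. Since the planthopper members did not pass with an estimated correlation, this explanation and an effect of the treatment both stay open. Over the 10 splits, too few for a share under 0.05, the real one alone gave a camera result as small as 1.09e-06, the smallest of the 9 others was 0.00021, and 3 of them were under 0.05.

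For the count of genes past the threshold, 3 of the 10 splits of the libraries, the real one included, gave as many as the real 1, and the highest other gave 1. For unadjusted p under 0.05, 4 of the 10 splits, the real one included, gave as many rows as the real 860, and the highest other gave 2207. These splits are too few for a share under 0.05.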
